A study of Mus musculus with 6 samples.

How the data were processed

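Total RNA from dissected mouse midbrain floor plate and ventral lateral tissue was profiled on Affymetrix arrays, 3 samples per region, each a pool from 6 embryos at embryonic day 10.5. Per the labels, 5 ng of total RNA was amplified with the NuGEN Ovation system and biotin-labelled. The submitters' processing notes name RMA, a method that corrects background, normalizes by quantiles and summarises probes, usually on the log2 scale; a version is not given in the sources used here. The deposited values are centred: for 100% of the 45101 probe sets the median over the 6 arrays lay within 1e-05 of 0. They are therefore log ratios without an absolute level, and no statement on signal over background can be made from them. The log base, the centring step and the direction are not stated. Log2, with higher values for more RNA, was assumed.

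Probe sets were named with the platform annotation of GEO. There were 64 control probe sets, 34945 with 1 gene symbol, 932 with several and 9160 with none. Of those with 1 symbol 34741 had an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 changed their name. No genome build is given in the sources used here, so no coordinates are reported. The named probe sets covered 18193 genes, 9010 of them with more than 1 probe set.

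Groups, tests, alternatives, gene lists and the rule for named genes were set before the data were examined. That plan took, for each gene, the probe set with the highest mean and left out genes with low mean values. Centred values hold no mean level, so neither step could be made. Instead the probe set with the largest variance over all 6 arrays was taken, without use of the groups, and no gene was filtered out. This choice was made after the centring was seen and before any test was run. A large variance can come from a difference between the regions, so this choice favours the probe set that differs most; the probe set with the lowest ID number was added as an alternative for that reason.

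Differences (floor plate minus ventral lateral) were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all 18193 genes and a threshold of 0.05. Subtracting a constant from each probe set leaves these differences unchanged. The 27 gene lists, covering cell types, signalling pathways and possible contaminants, were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts within a list were given over all genes and adjusted over the list alone. List members for which no probe set was named singly here were not analysed here and are not reported. Named genes were the 10 with the largest log2 fold change in each direction among genes past the threshold with separated groups, up to 4 members per list past the threshold, and a fixed set of marker genes. The rule also asked for a group mean above the median of all genes, which has no meaning for centred values and was dropped. Genes named outside the rule are given as such.

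The fit was tested on simulated data with the samples' own spread over 18193 genes, 200 of them changed. It recovered 10% of genes changed by a log2 of 0.5, 68% at 1, 96% at 2 and 98% at 3, and called 4 unchanged genes. In 20 simulated sets with no change it called 0 genes, and camera called at most 1 list. Probe sets were simulated independently of each other, so these sets cannot say how camera behaves on lists whose genes vary together. In the real data the estimated correlation was 0.573 in the floor plate identity list and 0.651 in the pan-neuronal list. It was -0.022 in the motile cilia list and -0.073 in the alar midbrain list, both under the preset 0.01. Camera's unadjusted p for these lists still rose, from 2.2e-06 to 0.0072 and from 3.49e-08 to 0.00466. Their loss of the call with an estimated correlation therefore cannot be read as an effect of genes that vary together.

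The alternatives were further normalization (quantile, cyclic loess, centring of arrays), the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, a trended and robust eBayes, array weights, the replicate number as a block, other thresholds, every probe set on its own and leaving out each sample. The lowest-numbered probe set and a filter on variance were added after the data were seen. Cyclic loess and the trend of eBayes use the mean value of a gene over the arrays. In centred values that mean is no signal level. A call lost or gained there therefore cannot be read as an effect of scaling or level. The variance filter selects genes partly on the spread that eBayes uses. Its adjusted p-values cannot be set beside those of the main fit. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for names and plots, and statmod 1.5.0 in R.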

Results

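Gene expression was measured in 2 neighbouring pieces of the ventral midbrain of C57BL/6 mouse embryos at embryonic day 10.5. The first was the floor plate, the strip of cells at the ventral midline that secretes Sonic hedgehog. The second was the adjacent ventral lateral region, dissected so as not to overlap with it. Each region had 3 samples, and tissue of 6 embryos of mixed sex was combined for each. Total RNA (5 ng per sample) was amplified, biotin-labelled and hybridised to Affymetrix mouse arrays, giving 45101 probe sets on 6 arrays. The deposited values are log ratios of each probe set to its own median over the 6 arrays, so a gene's value says how the samples differ and not how strongly the gene is expressed. The log base and the direction are not stated and were taken as log2 with higher values for more RNA. The medians of the 6 arrays over all probe sets lay between -0.0031 and 0.0045. The number of arrays limits the precision, and the median SE of a difference was 0.148 on the log2 scale. The labels do not say whether a floor plate pool and a ventral lateral pool shared embryos, so the p-values measure only the spread between these 6 samples.

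The comparison asked which genes differ between the floor plate and the tissue beside it. Genes of the floor plate and of midbrain dopaminergic progenitors were higher in the floor plate samples, together with genes of motile cilia and, on balance, of BMP and TGF-beta signalling. Genes of GABAergic neurons, of ventrolateral progenitors and of Hedgehog reception were lower there. So were alar midbrain genes, which were listed as a check for dorsal tissue in the dissected pieces. Camera called each of these lists at a preset correlation and none of them with an estimated one (adjusted p of 0.077 to 0.103). Of 18193 genes, 816 were higher and 603 lower in floor plate (limma, Benjamini-Hochberg adjusted p under 0.05), which is 7.80% of those tested. Among them 418 were at least 2-fold higher and 272 at least 2-fold lower. The 3 floor plate values lay entirely on one side of the 3 ventral lateral values for 25.8% of all genes, where chance gives 10%, and for each of the 1419 genes that passed the test. The first principal component held 62.2% of the variance and separated the regions, with scores of -34.97 to -28.03 in floor plate and 24.76 to 39.77 in ventral lateral samples. Leaving out any 1 sample, and so fitting fewer, lowered both counts, to 562 to 669 higher and 367 to 489 lower genes. The count of lower genes was 385 without floor plate replicate 1, 367 without floor plate replicate 3 and 381 without ventral lateral replicate 1. The count of higher genes in these fits was 565, 564 and 562. Of the 872 genes past the threshold with more than 1 probe set, 659 had all their probe sets on the same side.

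Corin, a transmembrane serine protease, was the gene with the highest fold change, 82.2-fold higher in floor plate (log2 fold change 6.36, SE 0.64, adjusted p = 0.000827). Its log2 value was 2.36 ± 0.15 (SD, n = 3) in floor plate and -4.00 ± 1.56 (SD, n = 3) in ventral lateral samples. The log2 fold change was 7.26 without ventral lateral replicate 2 and 4.49 after cyclic loess. The retinaldehyde dehydrogenase gene Aldh1a1 (log2 fold change 5.20), the Wnt enhancer gene Rspo2 (4.66) and the secreted protease gene Adamts5 (4.61) followed. Metrnl, Ccdc3, Fam183b, Dkk2, Folr1 and Shisa9 made up the rest of the 10 highest, with log2 fold changes of 4.56 to 4.08. Aldh1a1 had a log2 fold change of 1.88 (adjusted p = 0.328) after cyclic loess, and it missed the threshold without floor plate replicate 1 (adjusted p = 0.0537). Rspo2 and Dkk2 also missed it after cyclic loess, which cut their log2 fold changes to 2.43 and 2.23 (adjusted p of 0.132 and 0.124), and all 3 did with a trended and robust eBayes, which left the fold changes as they were. These 2 alternatives use the mean of a gene's values over the arrays, which in centred values is no signal level. The losses therefore cannot tell whether the 3 genes depend on scaling. Rspo2 had a log2 fold change of -0.04 on its other probe set, and Shisa9 one of 0.49 when probe sets that may cross-hybridise were left out, while Adamts5 was at 2.90 and Metrnl at 1.89 on the mean of their probe sets. On the other side, the homeobox gene Shox2 was 33.0-fold lower in floor plate (log2 fold change -5.05, SE 0.23, adjusted p = 2.27e-05), at -2.45 ± 0.29 (SD, n = 3) against 2.60 ± 0.41 (SD, n = 3). On its lowest-numbered probe set the log2 fold change was -1.71 (adjusted p = 0.00438). The AP-2 factor gene Tfap2b (-4.86), the homeobox gene Six3 (-4.79) and the growth factor gene Fgf15 (-4.71) came next. The LIM homeobox genes Lhx2 (-4.68) and Lhx9 (-4.47) were lower too, as were Gad1 (-4.56), which encodes a GABA-synthesising enzyme, and the vesicular GABA transporter gene Slc32a1 (-4.48). Crabp1, encoding a retinoic acid-binding protein, fell by 4.51 with an SD of 0.02 among ventral lateral samples, and Gata2 fell by 4.41.

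Every measured member of the floor plate identity list was higher in floor plate, 10 of 10 genes, and again 10 when adjusted over the list alone. The median log2 fold change was 1.90, with Corin (6.36), the axon guidance ligand gene Slit2 (3.70), the forkhead factor gene Foxa1 (2.70) and Slit1 (2.26) leading. Foxa2 was 3.39-fold higher, at 0.66 ± 0.07 (SD, n = 3) against -1.10 ± 0.64 (SD, n = 3). Shh itself was also 3.39-fold higher but close to the threshold (log2 fold change 1.76, SE 0.43, adjusted p = 0.0462). Its adjusted p was 0.13, 0.111 and 0.128 without floor plate replicate 1, 2 and 3 and 0.118 without ventral lateral replicate 1, and its other probe set gave a log2 fold change of 0.16. It passed in 8 of 16 alternatives. The list was shifted in camera of limma (adjusted p = 9.06e-14), and adjusted p = 0.103 with an estimated correlation. The mean of this list differed among ventral lateral samples, at -0.86 in replicate 2 against -1.51 in replicate 1 and -2.05 in replicate 3. Without ventral lateral replicate 2 the count was again 10 of 10, and without replicate 1 it was 9.

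Midbrain dopaminergic progenitor genes were higher as well, 9 of 13 with none lower, and 11 when adjusted over the list alone. The median log2 fold change was 2.43. Aldh1a1 (5.20), Rspo2 (4.66) and the LIM homeobox genes Lmx1b (3.72) and Lmx1a (3.71) led the list. Lmx1b was at 0.74 on its other probe set (adjusted p = 0.0182 with the lowest-numbered probe sets, which gave a list median of 0.80). Lmx1a was at 1.61 ± 0.06 (SD, n = 3) in floor plate and -2.11 ± 0.52 (SD, n = 3) in ventral lateral samples. The homeobox gene Msx1 was 11.6-fold higher on its main probe set, but its other probe set gave a log2 fold change of 0.44 that missed the threshold. Wnt1 missed the threshold despite a log2 fold change of 3.40 (SE 0.96, adjusted p = 0.0752). Its ventral lateral values were -5.10 in replicate 1, -0.91 in replicate 2 and -1.20 in replicate 3. Wnt1 passed without replicate 1 (log2 fold change 2.06, adjusted p = 0.000777), without replicate 2 (4.15, adjusted p = 0.0435) and after quantile normalization (3.03, adjusted p = 0.0369). A variance filter gave an adjusted p of 9.38e-09 at the unchanged log2 fold change of 3.40. That filter selects genes partly on the spread that the test uses, so no weight is put on this value. The list was shifted in camera (adjusted p = 2.01e-12), and adjusted p = 0.0997 with an estimated correlation. The list mean was -0.83 in ventral lateral replicate 2 against -2.37 and -1.67 in replicates 1 and 3, and the count was 10 of 13 without replicate 1 and 10 of 13 without replicate 2.

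**Figure D1:**
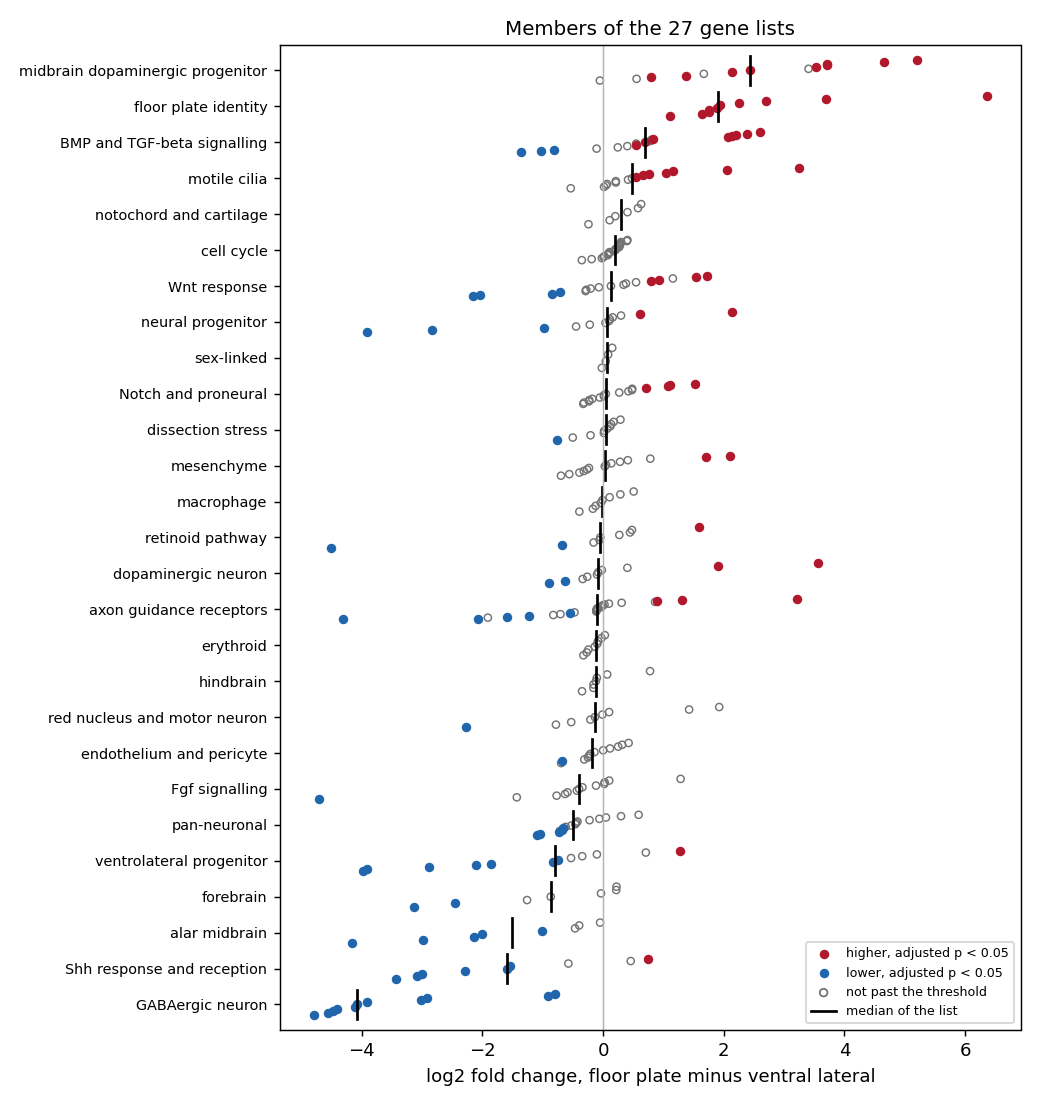
Each point is 1 gene of 1 of the 27 gene lists, placed on the horizontal axis at its log2 fold change (floor plate minus ventral lateral), with filled points past an adjusted p of 0.05 (red higher, blue lower), open points not past it and a black bar at the list's median. Every GABAergic neuron gene lies to the left, around a median of -4.09, and every floor plate identity gene to the right, around a median of 1.90.

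Genes of postmitotic dopaminergic neurons were split. Th, encoding tyrosine hydroxylase, was 11.9-fold higher in floor plate (1.54 ± 0.17 against -2.03 ± 0.63, SD, n = 3 each) and the nuclear receptor gene Nr4a2 3.74-fold higher. Nr4a2 had a log2 fold change of -0.07 on its lowest-numbered probe set, while 4 of its 6 probe sets passed as higher on their own. The vesicular transporter gene Slc18a2 (-0.90) and the decarboxylase gene Ddc (-0.63) were lower, each with an adjusted p just under the threshold (0.0439 and 0.0342). Slc18a2 passed in none of the fits without a floor plate sample or without ventral lateral replicate 1 or 2 (adjusted p of 0.0522 to 0.133). Ddc passed in none without a floor plate sample or without ventral lateral replicate 1 or 3 (0.0681 to 0.108), nor on its lowest-numbered probe set (0.529) or on the mean of its probe sets (-0.44, adjusted p = 0.115). Pitx3 did not pass (log2 fold change 0.40, adjusted p = 0.146). Of 10 list members 2 were higher and 2 lower, or 3 and 3 adjusted over the list alone. The median of -0.09 and the mean of 0.35 differed in sign, and camera did not call the list (adjusted p = 0.948).

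GABAergic neuron genes were lower in floor plate, 11 of 11 members, and 11 when adjusted over the list alone. The median log2 fold change was -4.09, with Six3 (-4.79), Gad1 (-4.56), Slc32a1 (-4.48) and Gata2 (-4.41) at the far end. These values depended on the probe set, with log2 fold changes of -2.43 for Six3, -2.99 for Gad1 and -1.41 for Slc32a1 on the mean of their probe sets, each past the threshold, while another probe set of Six3 was at 0.0022 and the other 3 of Slc32a1 at -0.64, -0.36 and -0.17. Gad1 was at -2.41 ± 0.33 (SD, n = 3) in floor plate and 2.15 ± 0.19 (SD, n = 3) in ventral lateral samples. Camera called the list (adjusted p = 1.02e-19), and adjusted p = 0.077 with an estimated correlation. Without ventral lateral replicate 1 there were 10 lower members, and 11 without replicate 2. Ventrolateral progenitor genes, homeodomain and related factors of the basal plate, were mostly lower, 7 of 12 against 1 higher, or 9 and 2 adjusted over the list alone. Dbx1 (-3.98), Pax6 (-3.92), Nkx6-2 (-2.88) and Nkx2-2 (-2.11) led them, with Pax6 at -1.62 on the mean of its probe sets. Nkx2-2 was 4.32-fold lower, at -0.82 ± 0.03 against 1.29 ± 0.64 (SD, n = 3 each). Sim1 was the member that rose (log2 fold change 1.28, adjusted p = 0.0454), and it missed the threshold without any 1 of the floor plate samples or without ventral lateral replicate 1 or 3 (adjusted p of 0.0709 to 0.154), as it did on its lowest-numbered probe set (0.32, adjusted p = 0.217) and with array weights (0.0758). Nkx6-1 did not pass (0.71, adjusted p = 0.0634), but did without ventral lateral replicate 2 (0.93, adjusted p = 0.00844), after cyclic loess (0.80, adjusted p = 0.0479) and with a variance filter (0.0274). The last 2 have the limits given with the alternatives. The list's median was -0.79 (camera adjusted p = 4.54e-06), and adjusted p = 0.077 with an estimated correlation. Red nucleus and motor neuron genes had 1 of 9 members lower, or 2 lower and 1 higher adjusted over the list alone, and the list was not called (median -0.14, adjusted p = 0.332). The 1 was Pou4f1, a POU factor gene of the red nucleus (log2 fold change -2.27).

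**Figure D2:**
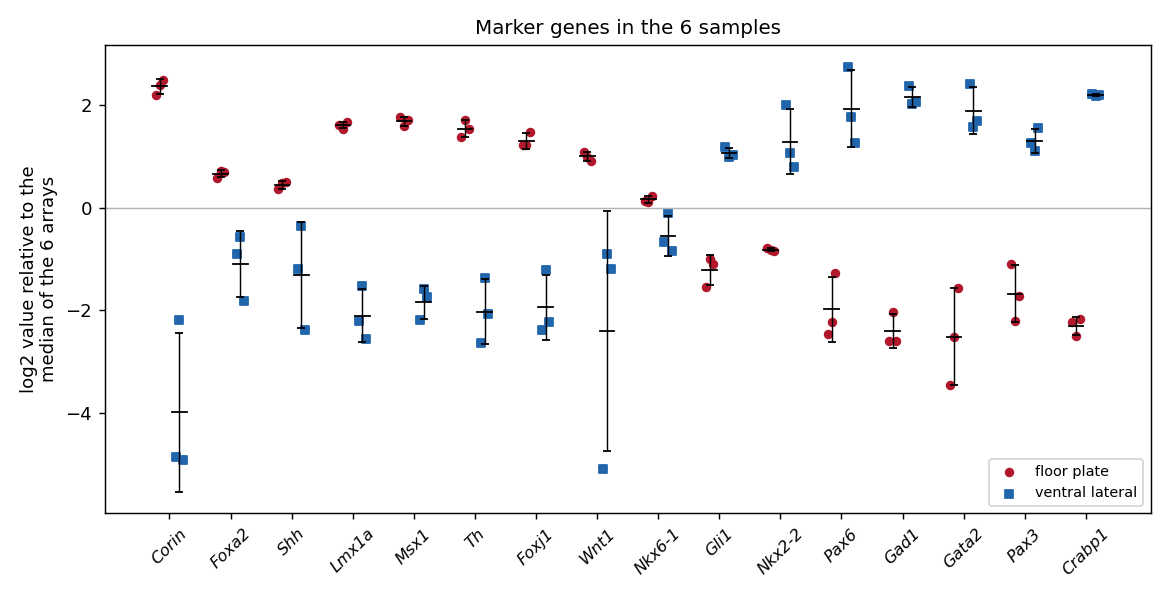
The vertical axis gives the log2 value relative to the median of the 6 arrays for 16 marker genes, with 1 point per sample (red circles floor plate, blue squares ventral lateral) and bars at the mean ± SD of 3 samples. Corin lies at 2.36 in floor plate and -4.00 in ventral lateral samples, Crabp1 at -2.31 and 2.20, and the Wnt1 values of the ventral lateral samples spread from -5.10 to -0.91.

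Hedgehog reception and response genes were lower in the floor plate, the tissue in which Shh was higher. The list pools receptors, transcription factors and target genes, so its direction does not measure the activity of the pathway. Of 9 members 6 were lower and 1 higher, or 6 and 2 adjusted over the list alone, with a median log2 fold change of -1.59. The transcription factor genes Gli2 (-3.43) and Gli3 (-2.99) and the Hedgehog-binding Hhip (-3.08) led, followed by the target gene Gli1, at -1.22 ± 0.29 in floor plate and 1.07 ± 0.09 in ventral lateral samples (SD, n = 3 each). On the lowest-numbered probe set the log2 fold change was 0.03 for Gli3 and -1.63 for Hhip. Of the 3 probe sets of Gli3, 2 passed as lower on their own. The receptor gene Ptch1 did not pass (-0.58, adjusted p = 0.287). The member that rose was the co-receptor gene Cdon (0.75, adjusted p = 0.0239), named after its value was seen, and no member was higher without floor plate replicate 1 or 2 or without ventral lateral replicate 1 or 2. Camera called the list (adjusted p = 4.2e-06), and adjusted p = 0.103 with an estimated correlation.

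BMP and TGF-beta genes rose on balance, 8 of 17 higher and 3 lower, or 11 and 3 adjusted over the list alone, with a median log2 fold change of 0.70. The ligand genes Bmp5 (2.61), Bmp7 (2.39), Tgfb3 (2.20) and Bmp6 (2.13) led. Bmp5 was at 1.26 ± 0.02 in floor plate and -1.35 ± 0.11 in ventral lateral samples (SD, n = 3 each), but its other probe sets gave log2 fold changes of 1.20 and 0.10, of which the second did not pass (adjusted p = 0.809). The target genes went both ways, and those given here were named after their values were seen: Id1 (-0.82) and Id2 (-1.36) were lower, as was the ligand gene Bmp2 (-1.03), and Id3 (0.70), Bambi (0.83) and Smad7 (0.54) higher. Camera called the list (adjusted p = 6.69e-06), and adjusted p = 0.077 with an estimated correlation, and the count of higher members was 5 without floor plate replicate 2. Wnt response genes went both ways, 4 higher and 4 lower of 17, or 7 and 4 adjusted over the list alone. Dkk3 (1.54) and the target gene Sp5 (1.73) were higher, and Tcf7l2 (-2.15) and the Wnt antagonist gene Sfrp1 (-2.04) lower. Sp5 missed the threshold without any 1 of the floor plate samples or without ventral lateral replicate 1 or 3 (adjusted p of 0.1 to 0.137), and with all 6 samples after cyclic loess (log2 fold change 1.34, adjusted p = 0.144), with a trended and robust eBayes (0.185), with array weights (0.0858) and with the lowest-numbered probe sets (0.0575). Tcf7l2 missed it without floor plate replicate 1 (0.0755). Dkk3 had an adjusted p over the threshold on its lowest-numbered probe set. The Wnt list was not called (median 0.13, adjusted p = 0.625), and its higher members numbered 1 without ventral lateral replicate 1. Notch and proneural genes had 4 of 17 higher and none lower, and 4 adjusted over the list alone. These were the Notch target genes Hey2 (1.53), Hes1 (1.10) and Hey1 (1.07) and the glycosyltransferase gene Mfng (0.70). Hey2 missed the threshold without floor plate replicate 1 (adjusted p = 0.05) or 2 (0.0531) or ventral lateral replicate 1 (0.0675). The Notch list was not called (median 0.05, adjusted p = 0.109), but was without floor plate replicate 1 (0.0435) or ventral lateral replicate 1 (0.0245). Of the Fgf signalling genes 1 of 13 was lower, and 1 adjusted over the list alone, namely Fgf15, at -2.31 ± 0.70 against 2.40 ± 0.63 (SD, n = 3 each). The Fgf list was not called (median -0.40, adjusted p = 0.124). Its mean in ventral lateral samples was -0.87 in replicate 1 against 0.81 and 1.11 in replicates 2 and 3, and without replicate 1 it had 5 lower members and was called (adjusted p = 7.47e-07).

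Genes of motile cilia were higher in the floor plate, 7 of 15 with none lower, or 8 adjusted over the list alone. Foxj1, the master regulator of motile ciliogenesis, was 9.47-fold higher, at 1.30 ± 0.15 against -1.94 ± 0.64 (SD, n = 3 each). Pifo (2.06), the axonemal dynein gene Dnah9 (1.16) and the tektin gene Tekt1 (1.04) followed. Tekt1 was lost without floor plate replicate 1 (adjusted p = 0.0577), and Dnah9 missed the threshold on its lowest-numbered probe set. The list's median was 0.48 (camera adjusted p = 7.42e-06), and adjusted p = 0.077 with an estimated correlation. The count of higher members was 3 without floor plate replicate 1 and 4 without ventral lateral replicate 3. None of 21 cell cycle genes passed on its own in limma, nor adjusted over the list alone, and 5 had an unadjusted p under 0.05. Camera still called the list (median 0.20, adjusted p = 0.0185), and adjusted p = 0.605 with an estimated correlation and 0.101 with fry, and it was lost without ventral lateral replicate 1 (adjusted p = 0.0789) and with cross-hybridising probe sets left out (median 0.13, adjusted p = 0.143), while the mean of probe sets gave a median of 0.081. Pan-neuronal genes were lower, 5 of 16, or 8 lower and 1 higher adjusted over the list alone, with a median of -0.49. Syt1 (-1.10), Ina (-1.05), Rtn1 (-0.73) and Nefl (-0.68) led. Rtn1 missed the threshold without floor plate replicate 1 or 3 or ventral lateral replicate 1 or 2 (adjusted p of 0.0642 to 0.0702), and Nefl in every fit that left out a sample but that without ventral lateral replicate 3 (0.0565 to 0.111), and on its lowest-numbered probe set (0.0634). On the lowest-numbered probe set the log2 fold change was 0.09 for Syt1, which also missed the threshold on the mean of its probe sets (-0.54, adjusted p = 0.0735), and -0.38 for Ina, and the list's median was -0.26. Camera called the pan-neuronal list (adjusted p = 0.000115), and adjusted p = 0.543 with an estimated correlation and 0.101 with fry. Its lower members numbered 2 without floor plate replicate 1 or 3, and 2 without ventral lateral replicate 1 or 2.

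Neural progenitor genes went both ways, 2 higher and 3 lower of 12, and the same counts adjusted over the list alone. The SoxB1 genes Sox1 (-2.83) and Sox3 (-0.98) and Pax6 (-3.92) were lower, and the glutamate transporter gene Slc1a3 was 4.42-fold higher on its main probe set. Of the other probe sets of Slc1a3 1 passed (log2 fold change 1.28), and the rest were at 0.05 to 0.64. Sox1 missed the threshold on its lowest-numbered probe set. The list's median of 0.07 and mean of -0.41 differed in sign, and it was not called (adjusted p = 0.866). Among axon guidance receptors and ephrins 3 of 24 were higher and 5 lower, or 4 and 8 adjusted over the list alone. Robo3, which lets commissural axons cross the midline, was 19.8-fold lower, and Nrp2 9.32-fold higher. Epha5 (-2.08) and Ephb1 (-1.59) were lower. On the lowest-numbered probe sets Robo3 and Epha5 missed the threshold and Nrp2 was at 0.97, past the threshold. The guidance list was not called (median -0.11, adjusted p = 0.0946), but was without floor plate replicate 2 (0.0267). Of 9 retinoid pathway genes 1 was higher and 2 lower, or 2 and 2 adjusted over the list alone. Crabp1 (-4.51) and Crabp2 (-0.69) were lower and the retinaldehyde reductase gene Dhrs3 3.03-fold higher, and the list was not called (median -0.05, adjusted p = 0.9).

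Markers of neighbouring tissue and of other cells were compared in the same way. Alar midbrain genes, which mark the dorsal midbrain, were lower in the floor plate samples, 5 of 8 with none higher, or 6 adjusted over the list alone. Mab21l2 (-4.17), Pax3 (-2.99), Pax7 (-2.14, and -1.40 on the mean of its probe sets) and Zic1 (4.01-fold lower) led. Zic1 missed the threshold without floor plate replicate 1 or 3 or ventral lateral replicate 2 or 3 (adjusted p of 0.0544 to 0.0868), or on its lowest-numbered probe set (0.0841). The alar list's median was -1.51 (camera adjusted p = 2.36e-07), and adjusted p = 0.077 with an estimated correlation, and 3 members were lower without floor plate replicate 1 or 3 or ventral lateral replicate 3. Dorsal tissue in the ventral lateral pieces could give such a pattern and was not tested. How far other genes lower in floor plate came from such tissue is therefore not known. Forebrain genes had 2 of 7 lower, Emx2 (-3.14) and Barhl2 (-2.46), and 2 adjusted over the list alone. Of the 6 fits that left out a sample, Barhl2 passed only in that without floor plate replicate 2 (adjusted p of 0.0582 to 0.1 in the other 5), and it missed the threshold with a trended and robust eBayes (0.119). The forebrain list was not called (median -0.87, adjusted p = 0.151), but was without floor plate replicate 2 (0.0436) and with a variance filter (0.000494), which has the limit given with the alternatives. Its median was -0.083 without ventral lateral replicate 2 (adjusted p = 0.413), and -1.37 and -1.35 without ventral lateral replicates 1 and 3. No member of the hindbrain (0 of 7, median -0.12, adjusted p = 0.653) or of the notochord and cartilage list (0 of 6, median 0.30, adjusted p = 0.124) passed in limma, nor adjusted over the list alone, and 2 of each had an unadjusted p under 0.05.

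Twist1 (2.11) and Postn (1.70) were higher in floor plate among 14 mesenchyme genes, and 2 adjusted over the list alone, while the list was not called (median 0.04, adjusted p = 0.543). The tight junction gene Cldn5 (-0.68) was lower among 12 endothelium and pericyte genes, 1 adjusted over the list alone, and that list was not called either (median -0.18, adjusted p = 0.332). Cldn5 missed the threshold without floor plate replicate 1 or 3 or ventral lateral replicate 1 (adjusted p of 0.068 to 0.0722). No erythroid (0 of 8, median -0.12, adjusted p = 0.346), macrophage (0 of 8, median -0.02, adjusted p = 0.948) or sex-linked gene (0 of 4, median 0.06, adjusted p = 0.866) passed in limma, nor adjusted over the list alone. At an unadjusted p under 0.05 there were 0, 2 and 0. The macrophage median lay below 0 and its mean (0.02) above. Among 10 dissection stress genes Atf3 was lower (-0.77), with 2 lower adjusted over the list alone, and it was lost without floor plate replicate 1 or ventral lateral replicate 1 or 3 (adjusted p of 0.0517 to 0.0553). The stress list had a median of 0.04 and a mean of -0.07 and was not called (adjusted p = 0.866). The difference between the 3' and 5' control probe sets, a measure of RNA quality that in centred values compares the arrays with each other and gives no absolute ratio, was 0.08 ± 0.15 in floor plate and -0.06 ± 0.09 in ventral lateral samples for beta-actin, and -0.0054 ± 0.075 and -0.031 ± 0.045 for Gapdh (SD, n = 3 each). None of the 10 lists called by camera was called with an estimated correlation. For the motile cilia and alar lists that correlation lay under the preset one, so correlated genes do not account for the loss there.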

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

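The tests of ventral lateral replicates 1 and 2 below were chosen after the values were seen. Among 10092 probe sets without a single gene name, which entered no comparison above, 60 were higher and 41 lower in floor plate (limma, Benjamini-Hochberg adjusted over these probe sets). None of the 64 control probe sets passed in limma, 2 had an unadjusted p under 0.05, and the largest absolute log2 difference among them was 0.303.

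Ventral lateral replicate 2 lay nearer the floor plate samples than replicates 1 and 3 did, with first component scores of 24.76 against 39.77 and 33.26. Corin was at -2.20 there against -4.87 and -4.92, Aldh1a1 at -1.26 against -4.90 and -5.07, and the mean of the floor plate identity list at -0.86 against -1.51 and -2.05. A compression of this array's signal that takes an equal share from all genes is argued against. Here 95 genes low in floor plate lost 0.102 of their difference and 146 genes high in floor plate 0.256, a ratio of 0.397. A compression of low signals only was not tested, and centred values hold no level to test it with. The SD over all probe sets was lowest on this array, at 0.225 against 0.234 to 0.294 on the others. A share of floor plate tissue in this pool is a candidate explanation, and the difference between the lost shares, 0.154, goes the way it needs, against -0.036 and -0.076 in replicates 1 and 3. The 95% bootstrap interval of 0.110 to 0.210 resampled genes within this 1 pool and does not measure the spread between samples. Each replicate was set against the other ventral lateral samples. Replicate 2 was thus part of the reference for replicates 1 and 3, which are not independent controls. The position of the dissection, which could give the same pattern, stays open: the forebrain genes Dlx1 (2.88) and Dlx2 (2.80) were also higher in this pool than in replicates 1 (-0.12 and 0.82) and 3 (-0.08 and -0.07), and no test separated position from floor plate tissue.

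Ventral lateral replicate 1 had lower values of Fgf genes than the other ventral lateral samples, with Fgf17 at -3.42 against 2.31 and 3.56 and Fgf18 at -1.16 against 0.77 and 1.38. Noise over the whole array is argued against by Pax5 and Cnpy1, isthmus markers outside the Fgf list: their mean difference from replicates 2 and 3 (-1.74) lay at percentile 0.01 of 10000 random pairs of genes of like spread. Tissue from near the isthmus, the Fgf-secreting boundary of midbrain and hindbrain, may have been present in replicates 2 and 3 and not in 1. The 5 isthmus markers Pax5, Cnpy1, Pax8, En1 and En2 had a median difference of -2.43 and lay lower in replicate 1, although the midbrain also expresses En1 and En2, which the dopaminergic progenitor list holds. A difference in embryo age between pools was not tested.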

How the results depend on the processing

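The lowest-numbered probe set, the variance filter and the reading of other splits were chosen after the data were seen. The planned filters on mean level were not run, because centred values hold no level, and what signal over background limits cannot be said. Quantile normalization, cyclic loess, centring of arrays, array weights and a trended eBayes gave 816 to 887 higher and 594 to 712 lower genes. The lowest-numbered probe set gave 679 and 497 (614 and 426 shared, and 1 called in the opposite direction). The variance filter gave 837 and 657 among 9097 genes and 12 lists (Fgf signalling 0.0488, Notch 0.0388 and forebrain 0.000494 added, cell cycle lost at 0.53), with Wnt1 at an adjusted p of 9.38e-09 (0.000777 to 0.323 elsewhere). Because that filter selects genes partly on the spread that eBayes uses, its adjusted p-values cannot be set beside the others. Every probe set on its own gave 1214 and 897. Stricter criteria gave fewer by construction, 428 and 271 at adjusted p under 0.01, and 418 and 272 at 2-fold. Leaving out a sample gave 562 to 669 higher, 367 to 489 lower genes and 10 to 12 lists; fewer samples were fitted. An estimated correlation called 0 lists and fry 11, without pan-neuronal and cell cycle (adjusted p of 0.101 each) and with red nucleus and motor neuron (0.0232), axon guidance (0.0218) and retinoid (0.00397). The replicate block gave 742 and 556 genes and 11 lists, adding Fgf signalling (adjusted p = 0.0415, and 7.47e-07 to 0.703 elsewhere), and of the named genes past the threshold Ddc and Nefl were not called there (0.0615 and 0.0765). Deviations of same-numbered samples correlated at 0.014, 0.119 and 0.111 and others at -0.159 to 0.041, and floor plate replicate 1 correlated best with ventral lateral replicate 3. The numbers were therefore not used as pairs; shared embryos are neither shown nor excluded. In the 85 named genes over 16 alternatives, 1262 values kept side and direction, 87 lost the call, 7 gained it and 4 turned sign, all with the lowest-numbered probe set: Gli3 0.035, Nr4a2 -0.072, Rspo2 -0.040 and Syt1 0.091. Of 81 named genes past the threshold 54 passed in every alternative. Medians of uncalled lists near 0 turned sign, and the cause was not tested. With the mean of probe sets, neural progenitor was -0.011, mesenchyme -0.019 and sex-linked -0.030. Array weights gave macrophage 0.0078. The lowest-numbered probe set gave neural progenitor -0.050 and mesenchyme -0.012. The variance filter, with fewer genes, gave neural progenitor -0.45, retinoid 0.11, endothelium 0.0011, macrophage 0.049 and stress -0.21. Without 1 sample, neural progenitor ranged from -0.053 to 0.10, mesenchyme from -0.32 to 0.28, macrophage from -0.12 to 0.045, retinoid from -0.14 to 0.11, sex-linked from -0.092 to 0.17 and stress from -0.016 to 0.091. Of the 10 possible splits of the 6 samples, too few for a share under 0.05, 1, the real one, gave as many genes (816 and 603), and the highest other 0 in limma (at most 864 at an unadjusted p under 0.05, against 3580). For lists 2 gave 10 or more, the real one with 10 and another with 11.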

Other observations

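All tests in this part were chosen after the values were seen. Fisher's exact test treats the genes of a family as independent, although all were measured on the same 6 arrays. Its p-values may therefore be too small. Of all genes tested 4.485% were higher and 3.314% lower. Families were picked by gene symbol. In those named for the axoneme of motile cilia, 18 of 85 genes were higher in floor plate and none lower. Fisher's exact test, two-sided, gave adjusted p = 8.27e-07 over 26 tests of 13 families. Enkur (log2 fold change 3.74) and Cfap126 (3.33) led. The higher genes included Ift57, an intraflagellar transport gene that is not particular to motile cilia. Dnah9, Tekt1 and Rsph1 among them are also in the motile cilia list. Secreted ADAMTS proteases followed, 6 of 15 higher (exact adjusted p = 0.000245), with Adamts5 (4.61), Adamts9 (2.88) and Adamts12 (2.19), although 2 were lower. Of 42 collagen genes 9 were higher and none lower (exact adjusted p = 0.000536). Of 19 Wnt ligand genes 5 were higher and 1 lower (exact adjusted p = 0.00534 for higher; 3 higher with the lowest-numbered probe set), and 3 of 9 Dickkopf and R-spondin genes were higher (0.02), a count that dropped to 1 after cyclic loess or with the lowest-numbered probe set.

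Genes of AP-2 transcription factors were lower in floor plate, 4 of 5 (Fisher's exact test, adjusted p = 7.57e-05), with Tfap2b (-4.86), Tfap2a (-3.95), Tfap2d (-3.29) and Tfap2e (-2.51). LIM homeobox genes had 4 of 12 lower (exact adjusted p = 0.00249), and 2 higher, Lmx1a and Lmx1b. Neuropeptide genes had 4 of 18 lower (exact adjusted p = 0.00937), Pnoc (-3.07), Sst (-1.91), Npy (-1.80) and Nts (-0.87), and 2 higher. Heparan sulfate enzymes had 3 of 15 lower (0.0354) and 2 higher, but 1 lower and 3 higher with the lowest-numbered probe set. Ribosomal protein genes (0 of 43 called), solute carriers (11 higher and 11 lower of 334), potassium channels (6 and 6 of 80; 5 and 1 with the lowest-numbered probe set) and semaphorins (3 and 3 of 20) passed in neither direction (exact adjusted p of 0.0706 to 1). The counts of the axoneme, ADAMTS, collagen and AP-2 genes stayed on the same side after quantile normalization, cyclic loess and centring of arrays.

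The neighbouring imprinted genes Dlk1 (log2 fold change -2.98), Meg3 (-2.44), Rian (-2.01) and Mirg (-2.27) were lower in floor plate together, and a faulty probe set is argued against by 19 of 19 probe sets with a negative difference, 18 of them past the threshold. The pan-neuronal list was also lower, with 13 of 16 members negative, but it fell less, with a median of -0.493 and a lowest member of -1.10. Centred values hold no level, so falls in 2 sets of genes with unlike background cannot be compared in size. Fewer neurons of all kinds in floor plate samples therefore stays open. A shift of imprinted genes in general is argued against by 38 others, with a median of -0.093 (95% bootstrap interval -0.214 to 0.107), 2 higher and 2 lower; that list was widened after values were seen, so that it held the imprinted genes already known to pass. A regional difference in the activity of this cluster is a hypothesis that the values leave open, as is a neuron type, such as GABAergic, that carries it. All 4 genes were lower under each of the 3 scalings. They were also lower on the mean of their probe sets and on the lowest-numbered one, with medians nearer 0, at -1.66 and -1.87.

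The mean of the mesenchyme list was 0.55 in floor plate replicate 2 and 0.26 in ventral lateral replicate 2, and between -0.54 and -0.0013 in the other 4 samples.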
